A study of Homo sapiens with 32 samples.

How the data were processed

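The samples were single cells of SK-N-SH, an established human neuroblastoma cell line, grown without treatment and sorted singly into 384-well plates. Polyadenylated RNA was turned into libraries by MARS-seq, a plate method in which each mRNA molecule is tagged with a unique molecular identifier (UMI) before amplification. Per the labels, alignment used Bowtie2 2.1.0 and the genome build hg19. The counting tool, the annotation and the authors' cell filter are not given in the labels. The deposited table holds raw UMI counts per gene and cell, with 27044 gene rows, of which 15700 had any UMI, and 1176 cells, the number of cells the labels give. Whole numbers and totals that differ between cells were checked on the table. The table held 0 mitochondrially encoded genes and 0 ERCC spike-ins, so neither was used as a filter or a scale. There were 690 gene rows with several names, which took 6.39 percent of the UMIs. Such a row is given under its leading name, and its UMIs cannot be divided between the genes.

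The 32 samples belong to 1 group. The deposited cell map, a text listing, gives each cell the 8 sample titles of its amplification batch rather than 1 title. Cells could therefore be placed in 4 batches of 8 samples, and the batch was the replicate (n = 4), in place of the 32 replicates laid out before the data were examined. All batches came from 1 line in 1 condition. They carry the technical spread between amplification batches, and no p-value measures a spread between cultures. With 4 batches an exact sign-flip test cannot give a two-sided p below 0.125. The cell filter, clustering parameters, markers, gene lists, tests and rule for named genes were set before the data were examined.

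Cells with at least 500 UMIs were kept, which left all 1176 cells, as the lowest total was 1211. Each UMI was put at random, with probability 0.5, into a clustering set or a test set. This kept the counting noise that shaped the clusters out of the tests. Other differences between the cells are held by both sets, so the tests are not independent of the clustering. The clustering set was scaled to the median total and log-transformed, and the 2000 most variable genes were used without the 524 genes of the gene lists and markers. Cells were clustered on 20 principal components and 15 neighbours by Leiden at resolution 0.5 (scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, Python 3.11.15). No doublet caller was used. A cluster was named for a cell class if at least 2 of its 10 leading genes by fold over all other cells were markers of that class, none marked another class, and at least 3 of the class's markers were higher than in the other cells. These minimums were set after the clusters were seen, and the markers before. Leading genes needed 50 CPM (counts scaled to 1e+06 per library) in the cluster or outside it, with 5 CPM added for the fold. Clusters that met no class kept their number. In alternatives where no cluster met a class, the cluster with the most extreme marker score stood in for it.

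Test-set UMIs were summed per batch and cluster and compared in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM scaling, the filterByExpr filter, the batch as a block and the quasi-likelihood test. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. The test shares its estimate of spread between genes, so a very small p does not show that a gene's own 4 batches were alike. Between cluster 1 and adrenergic-like cells, RPL28 was called with its direction in 2 of 4 batches (edgeR adjusted p = 0.0483). The planned comparison was between mesenchymal-like and adrenergic-like cells, in 8 summed libraries. The other 3 comparisons, each between neighbouring clusters in a fit of all 16 summed libraries, were chosen after the clusters were seen. Levels are means of CPM in the test set with the SD over 4 batches. Folds are those fitted by edgeR, except in genes with few counts. Where a group had 0 UMIs, the fold is given as at least the ratio to a floor of 3 UMIs over the whole group. Where it had 1 to 3 UMIs, the ratio of summed counts is given with its exact 95 percent interval. That interval, like the floor, covers counting error only. Against 0 UMIs the exact interval reaches lower than the fold from the floor. Between mesenchymal-like and adrenergic-like cells it starts at 15 for CAV1, where the floor gives 18.6, and at 82.2 for SHD, where it gives 104. The floor stood at 3.24 CPM in cluster 1, 4.18 CPM in cluster 2, 5.85 CPM in mesenchymal-like cells and 30.5 CPM in adrenergic-like cells. On simulated data of the same depth, edgeR recovered 51.1 percent of 2-fold and 94.9 percent of 4-fold changes, and 0.699 percent of its calls were false. The simulation gave every gene the same spread beyond batch effects and changed 200 genes, equally many up and down. It therefore does not measure false calls from gene-specific spread or from scaling.

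There were 17 gene lists. A list was tested with camera at a preset correlation of 0.01 between genes where at least 5 members were tested, with adjustment over the lists, and again with an estimated correlation. The test fry gave the direction and p of a list by itself, adjusted over the lists in the same way. Named genes were up to 4 called members per list by size of log2 fold with at least 20 CPM in either group, and the 8 largest changes each way with at least 50 CPM that kept their direction in at least 75 percent of batches. Other members are named only where they complete a list's count and were then chosen after their values were seen. Markers and the 10 leading genes of each cluster are not given as results.

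Cells were called cycling with at least 2 UMIs of the S phase and G2 and M phase lists after thinning test-set UMIs to 976 per cell, the 20th percentile, which left out 235 cells. The correlation of marker sums across cells used all UMIs thinned to 1973 per cell, with 200 random pairs of gene lists of like expression as background. Shares of cells carry exact Clopper-Pearson intervals. The spread of the share between batches was tested with 100000 permutations of cells over batches (scipy 1.17.1).

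After the clusters were seen, log2 folds were set out by chromosome and by gene order. Names were matched to a RefSeq table of assembly GRCh38.p14 for 3993 of 4039 tested genes (98.9 percent), and only the chromosome and the order of genes were taken from it, because no annotation of hg19 was at hand. The X and Y chromosomes were left out, which left 3873 genes on 22 autosomes. Chromosome medians were compared with 1000 random regroupings of the genes. A step in gene order, with at least 20 genes on each side and folds limited to 2 on the log2 scale, was compared with the largest steps in 1000 shuffles. On simulated data, a shift of log2 0.58, as from 2 to 3 copies, over 93 genes was found in 20 of 20 runs of the comparison of mesenchymal-like cells with cluster 2 and in 12 of 20 runs of that of adrenergic-like cells with cluster 1. Runs with no shift gave 0 false steps in 20, and the test of chromosome medians between mesenchymal-like cells and cluster 2 gave 2 false calls in 20.

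The alternatives tried were other resolutions, k-means in place of Leiden, lists kept in the clustering, other seeds, clusters from all UMIs, cells without the top 5 percent by UMIs or with at least 2000 UMIs, RLE scaling, library size alone, no filter on low counts, no batch block, DESeq2 1.42.0, limma voom, other thresholds for cycling, other correlations, and each batch left out in turn. Some single genes that passed or did not pass the tests are not reported here.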

Results

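Single cells of SK-N-SH, a neuroblastoma line long known to hold neuron-like and substrate-adherent cells, were profiled without treatment. The 32 samples made up 1 group and fell into 4 amplification batches of 8 samples. In all, 1176 cells carried 4507999 UMIs. Batch 1 held 275 cells with 1008261 UMIs, batch 2 held 319 cells with 1411284, batch 3 held 324 cells with 1156679 and batch 4 held 258 cells with 931775. Totals per cell ran from 1211 to 17021 UMIs, with a median of 3239 UMIs and 1643.5 genes. No label divides the cells, so the groups compared were clusters of cells. Levels are mean CPM ± SD over the 4 batches (n = 4), and adjusted p-values are from edgeR or camera.

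The series concerns subtypes of neuroblastoma, and the opening question was how many cells of the line belonged to each kind. Of the 1176 cells, 251 were mesenchymal-like (21.3%, exact 95% interval 19 to 23.8) and 47 were adrenergic-like (4.00%, 2.95 to 5.28). The other cells formed cluster 1, with 539 cells (45.8%, 43.0 to 48.7), and cluster 2, with 339 cells (28.8%, 26.3 to 31.5), which met no class. Over the batches the mesenchymal-like share was 21.2% ± 1.96 (SD, n = 4; range 19.3 to 23.2) and the adrenergic-like share 3.96% ± 0.894 (SD, n = 4). The mesenchymal-like share did not differ between batches beyond the sampling of cells (chi-square 2.01, permutation p = 0.574). It depended on the clustering: it was 8.59% at a Leiden resolution of 1.0 and 8.5% with clusters from all UMIs. At resolution 0.3 (47.7%) and with k-means into 2 clusters (55.3%) no cluster met the naming rule for mesenchymal-like cells, and the class was the cluster with the most extreme marker score, so the clustering and the rule changed together. The adrenergic-like share was 44.7% with k-means, also by score, and stayed between 3.66% and 4.42% in the other clusterings and cell filters.

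Marker levels describe how the clusters were named and are not results. The mesenchymal-like cluster met its class with the minimum of 2 markers among its leading genes, PRRX1 and COL1A1. PRRX1 lies on a part of chromosome 1 whose genes were higher as a block in these cells, so the name rests in part on it. STMN2, a regulator of microtubules in neurons, stood at 2330 ± 381 CPM in adrenergic-like cells, 765 ± 85.5 in cluster 1, 109 ± 41.7 in cluster 2 and 15 ± 17.4 in mesenchymal-like cells. COL1A1, a chain of collagen I, stood at 41.4 ± 50.6, 133 ± 24.3, 216 ± 98.4 and 2388 ± 327 CPM in the same order. TWIST1, a transcription factor on the mesenchymal marker list, went the other way, at 986 ± 411 CPM in adrenergic-like and 198 ± 46.4 CPM in mesenchymal-like cells. Of the 23 mesenchymal markers with any UMI, 13 were higher in the mesenchymal-like cluster than in the other cells. COL3A1, a chain of collagen III, stood at 109 ± 17.3 CPM there. It stood at 159 ± 48.1 CPM in cluster 1, 146 ± 62.8 in cluster 2 and 43 ± 66.9 in adrenergic-like cells. Markers of other cell types were near absent in the whole table, with 29 UMIs of Schwann cell precursor, 8 of endothelial, 3 of immune and 1 of epithelial markers. Erythroid markers had UMIs in 0 of 1176 cells, which allows a share of up to 0.255% of cells with such a UMI. UMIs per cell differed little between mesenchymal-like and adrenergic-like cells (mean log2 difference −0.09 ± 0.15, SD, n = 4; exact sign-flip p = 0.5; lower in 2 of 4 batches).

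**Figure D1:**
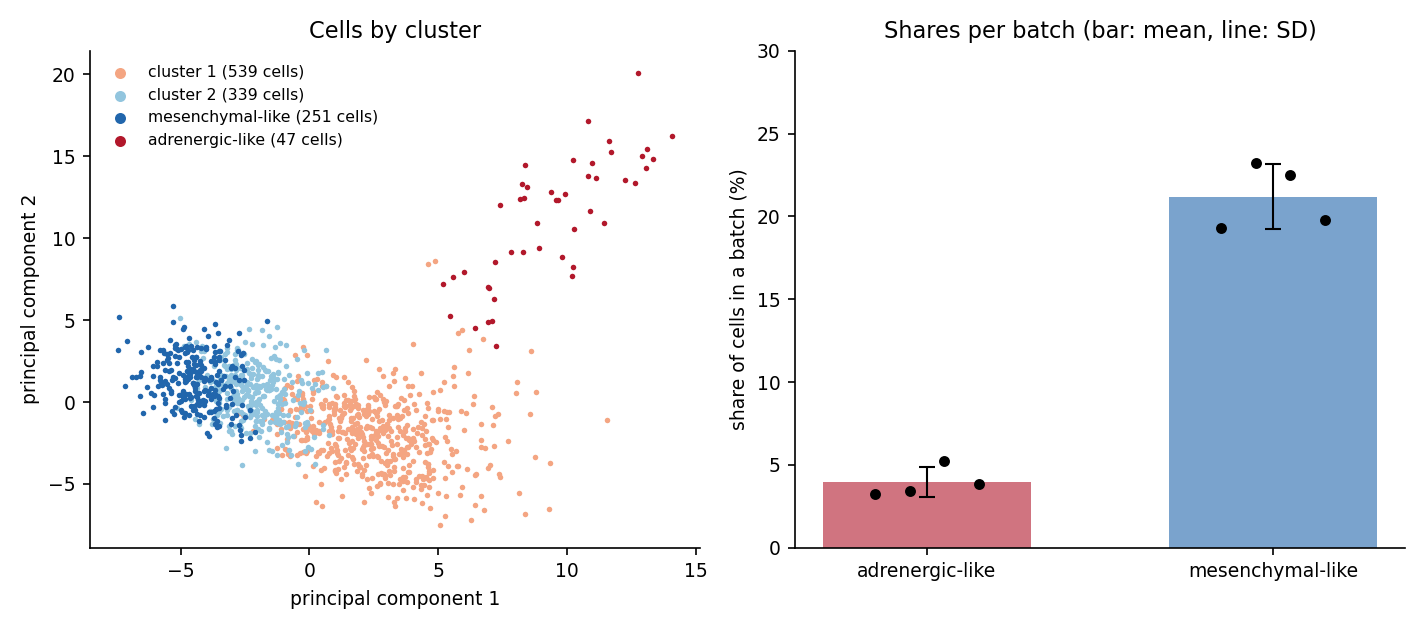
Cells on the leading principal components of the clustering set, coloured by cluster, and the shares of the adrenergic-like and mesenchymal-like cells in percent of the cells of a batch, with bars for the mean of 4 batches, error bars for the SD and points for batches. The mean shares were 3.96% and 21.2%.

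Do single cells carry both programmes or mostly 1 of them? Across cells at 1973 UMIs each (941 cells), adrenergic and mesenchymal marker sums were inversely related, with a Spearman correlation of −0.216 ± 0.0826 (SD over 4 batches; range −0.329 to −0.131; lower than 0 in 4 of 4 batches; exact sign-flip p = 0.125, the smallest p that 4 batches allow). Random pairs of lists of like expression gave a mean of −0.00407 (range of 95% −0.102 to 0.110), and 0 of 200 pairs were as low. The relation rested in part on the adrenergic-like cells: without them it was −0.114. That value lay below the 95% range of the random pairs but not below the lowest pair, −0.129. No random pairs are given without these cells. Even so, 83.1% of cells (exact 95% interval 80.6 to 85.4) held at least 1 UMI of each programme with VIM, an intermediate filament gene found at high levels in most cells, left out. In mesenchymal-like cells the median was 1 adrenergic and 16 mesenchymal marker UMIs, and 63.3% held both. In adrenergic-like cells the medians were 17 and 3, and 92.9% (80.5 to 98.5) held both. TWIST1, which was higher in adrenergic-like than in mesenchymal-like cells, was kept among the mesenchymal markers. With VIM left out it had the most test-set UMIs of them in adrenergic-like cells, 95, followed by THY1 with 28 and SPARC with 27. The share with both was not counted without TWIST1. The medians of cluster 1, 4 and 7, lay between those of mesenchymal-like and adrenergic-like cells, and 95.4% of its cells held both. Cluster 2 had medians of 2 and 7, and 78.4% of its cells held both. The data hold no cell type that lacks both programmes, so the part of single UMIs that is background is unknown.

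Mesenchymal-like cells were compared with adrenergic-like cells, the clusters furthest apart by marker score, to ask which genes set them apart. Such a difference does not order all clusters: TIMP1 averaged 1068 ± 154 CPM in cluster 1 and 924 ± 196 CPM in mesenchymal-like cells. Mesenchymal-like cells had higher levels of actin and adhesion genes, of matrix regulators such as TIMP1 and of interferon-inducible IFITM genes, and lower levels of neuronal cytoskeleton, DNA replication and several secretory genes. These are calls of single genes and of lists at a preset correlation, and 0 of 14 lists passed with an estimated one (camera, lowest adjusted p = 0.181, unadjusted p under 0.05 in 3), while fry passed 10. VIP, a neuropeptide, stood at 2996 ± 137 CPM against 67.2 ± 97.4 CPM (51.3-fold higher, log2 5.68 ± 0.30 SE, adjusted p = 1.57e-23). CRMP1, which acts in axon guidance, was 44.4-fold lower at 6.48 ± 9.64 against 434 ± 120 CPM. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was 11.2-fold higher at 1582 ± 342 against 160 ± 66.0 CPM. Each of these went the same way in 4 of 4 batches.

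In the actin cytoskeleton and adhesion list, 24 of 25 tested genes rose, 0 fell and 1 did not pass (camera adjusted p = 5.61e-20; adjusted p = 0.181 with an estimated correlation). CAV1, the coat protein of caveolae, had 558 ± 87.8 CPM and 0 UMIs in adrenergic-like cells, at least 18.6-fold higher. S100A11, a calcium-binding protein, was 23.1-fold higher, and TPM2, a tropomyosin, 16.6-fold higher at 1441 ± 97.2 against 85.1 ± 41.5 CPM. The integrin chain ITGA3 stood at 607 ± 136 CPM against 2 UMIs in all, a ratio of 29.9 (counting interval 8.22 to 248). ITGB1, the integrin beta 1 chain, was the member that did not pass, at 419 ± 171 against 380 ± 167 CPM. S100A11 and 4 more of the risen members lie on a part of chromosome 1 whose genes were higher as a block in mesenchymal-like cells.

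Of the extracellular matrix list, 6 of 13 tested genes rose, 0 fell and 7 did not pass (adjusted p = 0.0102; adjusted p = 0.362 with an estimated correlation). SERPINH1, a collagen chaperone, was 7.65-fold higher at 365 ± 72.4 against 57.1 ± 44.5 CPM, and TIMP1, an inhibitor of matrix metalloproteinases, 4.73-fold higher at 924 ± 196 against 213 ± 52.4 CPM. BGN, the proteoglycan biglycan, stood at 165 ± 55.5 CPM against 0 UMIs, at least 4.99-fold higher. Of the YAP and TAZ targets, 4 of 6 rose, 1 fell and 1 did not pass, and the list as a whole did not pass (adjusted p = 0.141). AXL, a receptor tyrosine kinase, was at least 9.40-fold higher at 280 ± 40.1 CPM against 0 UMIs, and CYR61, a secreted matrix protein, at least 4.41-fold higher at 145 ± 51.9 CPM against 0 UMIs. NT5E, which makes adenosine outside the cell, had a ratio of 36.9 (6.54 to 1463). AMOTL1, an angiomotin family member, was the gene that fell, by 5.99-fold. Of the interferon and antigen presentation list, 4 of 5 rose, 0 fell and 1 did not pass (adjusted p = 0.0120; adjusted p = 0.362 with an estimated correlation). IFITM2, which restricts viral entry, was at least 12.3-fold higher at 378 ± 26.2 CPM against 0 UMIs. The row of HLA-B, shared with HLA-C, was 5.17-fold higher, and B2M, their light chain, 3.91-fold higher at 174 ± 120 against 51.1 ± 43.2 CPM, in 3 of 4 batches.

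Of the neuronal cytoskeleton and axon list, 11 of 16 genes fell, 2 rose and 3 did not pass, and 3 rose when adjusted over the list alone (adjusted p = 0.000199; adjusted p = 0.260 with an estimated correlation). KIF1A, the motor of synaptic vesicle precursors, stood at 166 ± 49.0 CPM in adrenergic-like cells against 0 UMIs, at least 29.5-fold lower in mesenchymal-like cells. RTN1, a neuronal reticulon, was at least 27.8-fold lower. DCX, a microtubule protein of migrating neurons, fell as well and was among the 10 leading genes of the adrenergic-like cluster. The members that rose were DPYSL3, a relative of CRMP1, 4.66-fold, and UCHL1, a neuronal deubiquitinase, 1.34-fold in 3 of 4 batches. Of the secretory granule and transmitter list, 5 of 8 fell, 3 rose and 0 did not pass, and the list as a whole did not pass (adjusted p = 0.616), with a camera direction down and a fry direction up. SCG3, a granin, was at least 48.6-fold lower, in 3 of 4 batches. The neuropeptide gene GAL was 25.7-fold lower at 7.83 ± 9.83 against 266 ± 179 CPM, and NPY 5.96-fold lower at 64.6 ± 25.3 against 385 ± 293 CPM. The granins SCG2, 4.67-fold, and VGF, 1.48-fold in 3 of 4 batches, rose together with VIP. Of the 3 tested neuroblastoma-associated genes, too few for a camera test, SOX4, a transcription factor of neural progenitors, was 8.62-fold lower at 29.97 ± 22.4 against 274 ± 63.9 CPM. MDK, a growth factor, was 1.35-fold lower at 869 ± 149 against 1303 ± 238 CPM (adjusted p = 0.0371), a call that ended with no filter on low counts (log2 0.11). CCND1, cyclin D1, did not pass, at 268 ± 120 against 420 ± 102 CPM.

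**Figure D2:**
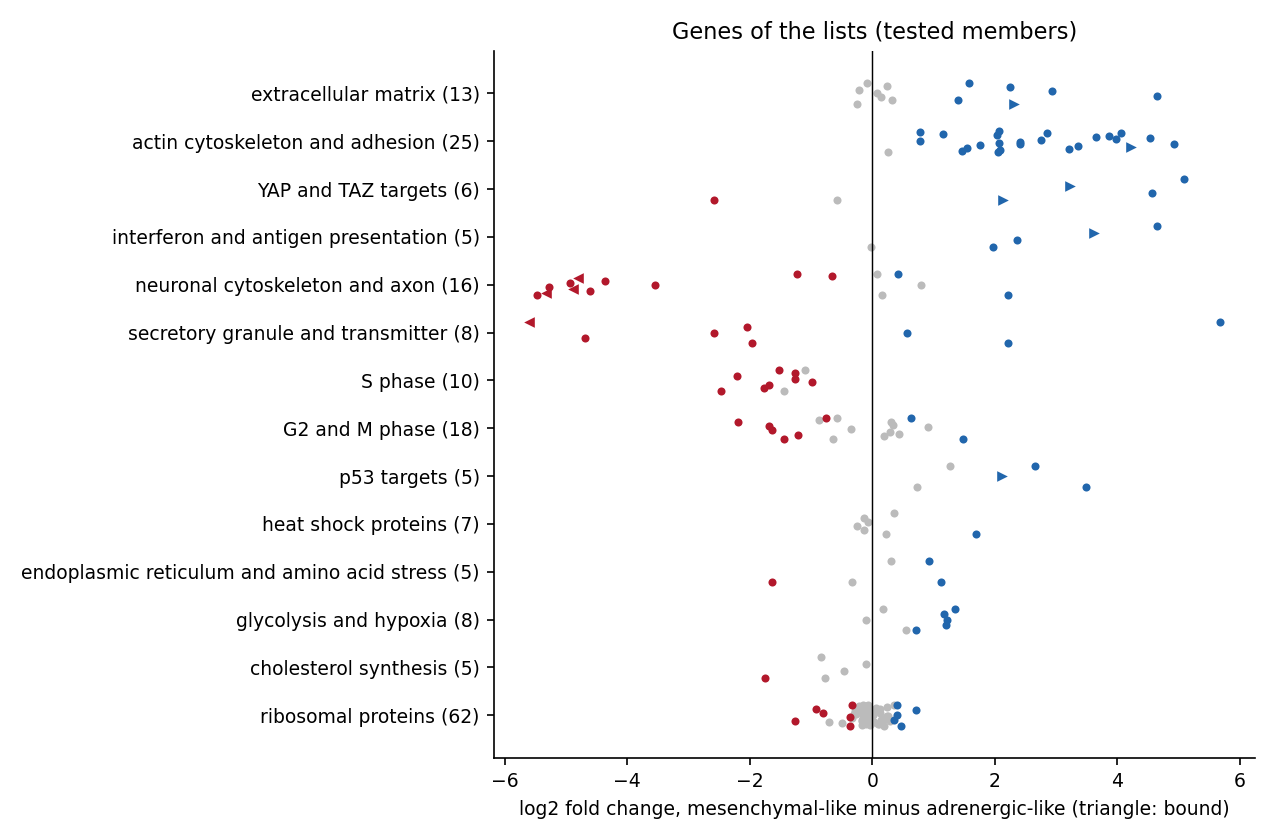
Log2 fold change of every tested member of each gene list, mesenchymal-like minus adrenergic-like cells, with called genes in blue where higher and red where lower, genes not called in grey, and triangles for bounds against 0 UMIs. Of the actin and adhesion genes 24 of 25 were higher and of the neuronal cytoskeleton genes 11 of 16 lower.

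Genes of DNA replication were lower in mesenchymal-like cells. Of the S phase list, 8 of 10 fell, 0 rose and 2 did not pass, and 10 fell when adjusted over the list alone (adjusted p = 0.000713; adjusted p = 0.181 with an estimated correlation). CLSPN, a checkpoint adaptor at the replication fork, was 5.50-fold lower at 40.1 ± 30.1 against 259 ± 115 CPM. The helicase subunits MCM2 and MCM4 were 3.41-fold and 3.20-fold lower, and RRM2, a ribonucleotide reductase subunit on a part of chromosome 2 that was lower as a block, 4.64-fold lower. Of the G2 and M phase list, 6 of 18 fell, 2 rose and 10 did not pass, and the list as a whole did not pass (adjusted p = 0.190). MKI67, the proliferation antigen Ki-67, was 4.54-fold lower at 87.4 ± 33.6 against 470 ± 233 CPM, and HMGB2, a chromatin protein, 3.22-fold lower. CDC20, the activator of the anaphase-promoting complex, was 2.78-fold higher and TUBB4B, a tubulin, 1.55-fold higher in 3 of 4 batches. The share of cells with at least 2 UMIs of these lists at equal depth was 88.4% ± 6.10 against 95.9% ± 4.93 (SD, n = 4), a difference of −7.58 ± 4.61 points that was below 0 in 4 of 4 batches (exact sign-flip p = 0.125, the smallest possible). It was 89.2% ± 1.51 in cluster 1 and 91.3% ± 2.53 in cluster 2, and the difference depended on the minimum, at −3.65 points with at least 1 UMI (in 3 of 4 batches) and −17.7 with at least 3. Few UMIs of the lists are needed for this share, so it is not a count of dividing cells.

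Stress and metabolic genes differed as well. Of the p53 targets, 3 of 5 rose, 0 fell and 2 did not pass, and 4 rose when adjusted over the list alone (adjusted p = 0.0103; adjusted p = 0.362 with an estimated correlation). GDF15, a stress-induced cytokine, was at least 4.35-fold higher at 137 ± 99.4 CPM against 0 UMIs, and RPS27L 6.31-fold higher. Of the glycolysis and hypoxia list, 5 of 8 rose, 0 fell and 3 did not pass, and 6 rose when adjusted over the list alone (adjusted p = 0.00229; adjusted p = 0.181 with an estimated correlation). PKM2, the row of pyruvate kinase, was 2.56-fold higher, LDHA, lactate dehydrogenase A, 2.33-fold higher and GAPDH 2.30-fold higher at 4559 ± 236 against 2109 ± 105 CPM. Among heat shock proteins, HSPB1 rose 3.22-fold and 6 of 7 did not pass (adjusted p = 0.616; median log2 −0.06 and mean 0.24). Of the endoplasmic reticulum and amino acid stress list, the chaperone CALR rose 2.18-fold and PDIA4 1.89-fold, while PHGDH, which starts serine synthesis, was 3.12-fold lower in 3 of 4 batches, and 2 did not pass (adjusted p = 0.431). The cholesterol synthesis list as a whole did not pass (adjusted p = 0.18). EGR1, an immediate early transcription factor and the only tested AP-1 list gene, was 3.11-fold lower at 55.1 ± 15.9 against 205 ± 191 CPM, in 3 of 4 batches. Of the ribosomal proteins, 5 of 62 rose, 6 fell and 51 did not pass (adjusted p = 0.443), whereas scaling by library size alone gave 1 higher and 24 lower (adjusted p = 0.00545). No mitochondrially encoded gene was in the table.

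Outside the lists and markers, the largest fitted differences were in genes with 0 UMIs on 1 side. Their rank rests on the fit, since the counts give only a lower bound for their folds. EMP3, an epithelial membrane protein (at least 14.7-fold), FOXD1, a forkhead transcription factor (at least 13.2-fold), and FXYD5, a regulator of the sodium pump (at least 12.9-fold), were higher in mesenchymal-like cells. SHD (at least 104-fold), AK131521 (at least 71.2-fold), C12orf34 (at least 57.3-fold) and COLEC11, a collectin (at least 53.8-fold), were lower. COLEC11 lies on the lower part of chromosome 2. MMP3, HMP19 and RPH3A also met the rule but were among the leading genes of the clusters. In all, 572 of 1714 tested genes were called, 295 higher and 277 lower in mesenchymal-like cells, of which 333 were neither used in the clustering nor on a list. The split of directions depended on scaling: library size alone called 232 higher and 366 lower, with the median gene moved from 0.02 to −0.17 on the log2 scale, and no filter on low counts called 1028, of which 81.8% were higher, with the median gene at 0.57. DESeq2 called 335, the fit without the batch block 358, all UMIs in place of the test set 1150, k-means classes 1098 and classes at resolution 1.0 called 361. Without the genes of the chromosome parts, 509 were called, 256 higher and 253 lower, 506 of them shared. Of 14 gene lists tested, 7 passed in camera and 10 in fry, among them the same 7. Without the chromosome parts 6 of 12 passed in camera, as the p53 list, which had passed, and the cholesterol list fell below the 5 members needed for a test.

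Cluster 1, the largest group and the nearest to adrenergic-like cells by marker score, was compared with them. Cluster 1 had higher actin, matrix and antigen presentation genes and lower neuronal cytoskeleton genes. ANXA2, a membrane-binding annexin, stood at 3749 ± 368 against 459 ± 246 CPM (8.70-fold higher, adjusted p = 9.46e-86). NEFM and INA, neurofilament chains, were 27.1-fold and 23-fold lower in cluster 1, INA at 8.0 ± 8.3 against 245 ± 50.2 CPM. Each went the same way in 4 of 4 batches.

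In cluster 1, 22 of 28 actin and adhesion genes were higher and 0 lower, 25 when adjusted over the list alone (adjusted p = 6.45e-32; adjusted p = 0.000668 with an estimated correlation). The actin-binding TAGLN was 8.89-fold and TPM1 6.42-fold higher. Of 21 matrix genes 10 were higher and 2 lower, or 12 and 2 over the list alone (adjusted p = 0.000415; 0.0416 with an estimated correlation), with SERPINH1 9.40-fold higher. Of 10 interferon and antigen presentation genes 7 were higher and 0 lower, or 8 and 0 over the list alone (adjusted p = 8.67e-05; 0.0416 with an estimated correlation). HLA-B was 7.57-fold higher at 480 ± 114 against 68.4 ± 50.9 CPM. Of 16 neuronal cytoskeleton genes 9 were lower and 2 higher, or 9 and 3 over the list alone (adjusted p = 1.82e-07; 0.0163 with an estimated correlation). Of 11 glycolysis genes 4 were higher and 0 lower, or 5 and 0 over the list alone (adjusted p = 0.00362; 0.0416 with an estimated correlation), among them PFKP, a phosphofructokinase, 3.26-fold. Of 9 endoplasmic reticulum stress genes 3 were higher and 0 lower, or 4 and 0 over the list alone (adjusted p = 0.04; 0.0884 with an estimated correlation). Of 21 S phase genes 4 were lower and 0 higher, 10 when adjusted over the list alone (adjusted p = 0.000203; adjusted p = 0.0562 with an estimated correlation), with PCNA, the DNA polymerase clamp, 2.05-fold lower. Of 33 G2 and M phase genes 4 were lower (adjusted p = 0.0400; adjusted p = 0.383 with an estimated correlation), with CENPF, a kinetochore protein, 2.75-fold lower. CYR61 was at least 7.48-fold higher at 228 ± 24.1 CPM against 0 UMIs, the sodium channel SCN9A at least 4.82-fold and MYLK, myosin light chain kinase, at least 4.57-fold. Of 13 secretory granule and transmitter genes 4 were lower and 3 higher, or 4 and 4 over the list alone, and the list did not pass (adjusted p = 0.132). In it the granin SCG3 was 34.1-fold lower in 3 of 4 batches, GAL 21.7-fold lower and VIP 10.5-fold higher. RET, a receptor tyrosine kinase, was 4.42-fold lower. MDK was 1.5-fold higher at 1702 ± 149 against 1303 ± 238 CPM, in 3 of 4 batches. In all, 643 of 4039 genes were called, 420 higher and 223 lower in cluster 1. Library size alone gave 306 higher and 332 lower, with the median gene moved from 0.16 to −0.03 on the log2 scale, DESeq2 gave 222 and 240, and no filter on low counts gave 874 and 131, with the median gene at 0.61.

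Cluster 2 was then compared with cluster 1, the other large group. Cluster 2 had more RNA of VIP, CAV1 and YAP and TAZ targets and less of neuroblastoma-associated genes. CAV1 stood at 233 ± 94.4 against 7.81 ± 11 CPM (28.2-fold higher, adjusted p = 1.49e-43) and VIP at 1729 ± 241 against 586 ± 73.4 CPM (2.95-fold higher). NCAM1, a neural adhesion molecule, was 6.78-fold lower at 46.6 ± 20.1 against 326 ± 47.5 CPM. Each went the same way in 4 of 4 batches.

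Of 12 YAP and TAZ targets 5 were higher in cluster 2 and 0 lower, 6 when adjusted over the list alone (adjusted p = 0.000466; 0.0318 with an estimated correlation). AXL was 4.57-fold higher at 413 ± 76.5 against 88.1 ± 10.1 CPM, and NT5E 3.58-fold higher. Of 6 neuroblastoma-associated genes 5 were lower (adjusted p = 6.14e-05; 0.0318 with an estimated correlation). RET had 0 UMIs in cluster 2, at least 6.46-fold lower, CHRNA3, a nicotinic receptor subunit, was 7.34-fold and SOX4 4.23-fold lower. Of 28 actin and adhesion genes 12 were higher and 4 lower, or 13 and 6 over the list alone (adjusted p = 6.14e-05; adjusted p = 0.117 with an estimated correlation), with S100A10 3.12-fold higher. Of 6 immediate early genes 3 were lower (adjusted p = 0.0105; adjusted p = 0.172 with an estimated correlation), with EGR1 3.27-fold lower. Of 10 interferon and antigen presentation genes 4 were lower and 0 higher, or 5 and 0 over the list alone (adjusted p = 0.0105; adjusted p = 0.172 with an estimated correlation), with B2M 1.98-fold lower in 3 of 4 batches. Of 9 p53 targets 3 were higher, or 4 over the list alone (adjusted p = 0.0102; adjusted p = 0.172 with an estimated correlation), with CDKN1A 1.89-fold. Of 11 glycolysis genes 3 were higher (adjusted p = 0.0182; adjusted p = 0.144 with an estimated correlation), with LDHA 1.63-fold. Of 21 matrix genes 3 were higher and 6 lower, or 3 and 9 over the list alone (adjusted p = 0.250), with COL6A2, a collagen VI chain, 3.02-fold lower. FOXD1 was 16.8-fold and KCNMA1, a potassium channel, 8.78-fold higher, and TMOD1, which caps actin filaments, 20.6-fold lower. In all, 560 of 4039 genes were called, 236 higher and 324 lower in cluster 2. DESeq2 called 287, the fit without the batch block 272 and the fit without batch 2 called 357.

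**Figure D3:**
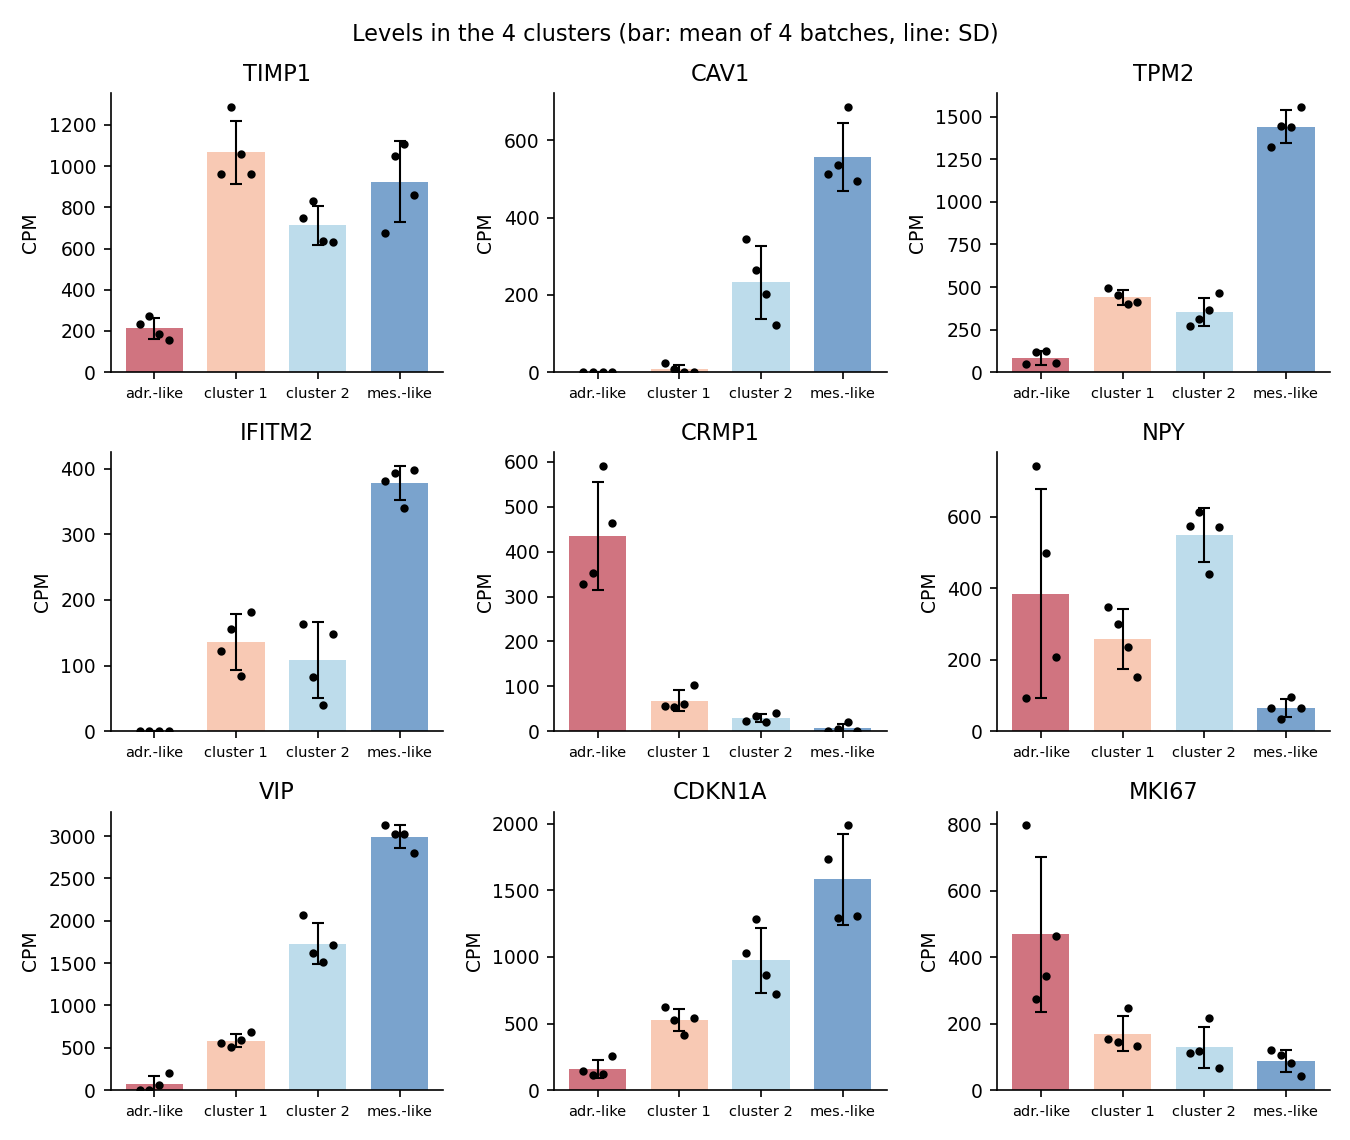
CPM of 9 genes in the adrenergic-like, cluster 1, cluster 2 and mesenchymal-like cells, with bars for the mean of 4 batches, error bars for the SD and points for batches. VIP ran from 67.2 to 2996 CPM along this order, and NPY was highest in cluster 2 at 550 CPM.

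Mesenchymal-like cells were last compared with cluster 2, the cluster next to them by marker score. They had more of several matrix genes, tropomyosin and IFITM genes and less NPY, and their genes on parts of chromosomes 1 and 2 were shifted as blocks. TPM2 stood at 1441 ± 97.2 against 353 ± 83.4 CPM (4.38-fold higher, adjusted p = 9.62e-71). NPY was 8.36-fold lower at 64.6 ± 25.3 against 550 ± 76.1 CPM, and IFITM3 8.62-fold higher at 286 ± 61.8 against 33.8 ± 14.5 CPM. Each went the same way in 4 of 4 batches.

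Of 21 matrix genes 7 were higher in mesenchymal-like cells and 2 lower, or 8 and 3 over the list alone (adjusted p = 0.00100; adjusted p = 0.158 with an estimated correlation). BGN was 7.15-fold and COL4A1, a collagen IV chain, 6.11-fold higher. Of 28 actin and adhesion genes 10 were higher and 0 lower (adjusted p = 3.16e-11; 0.0226 with an estimated correlation), with CAV1 2.49-fold and S100A6 2.44-fold higher. S100A6 and 3 more of the 10 lie on the chromosome 1 part, and without the genes of both chromosome parts 6 of 23 were higher (adjusted p = 3.36e-07; 0.0521 with an estimated correlation). Of 10 interferon and antigen presentation genes IFITM3 and IFITM2 (3.80-fold) were the 2 that were higher (adjusted p = 0.00342; adjusted p = 0.158 with an estimated correlation). Of 21 S phase genes 1 was lower, RRM2 of the chromosome 2 part (adjusted p = 0.0229; adjusted p = 0.289 with an estimated correlation). Of 33 G2 and M phase genes 2 were lower, GTSE1 and HMGB2, or 1 over the list alone (adjusted p = 0.0379; adjusted p = 0.538 with an estimated correlation). Of 68 ribosomal protein genes 7 were higher and 2 lower, or 15 and 2 over the list alone (adjusted p = 2.31e-06; 0.279 with an estimated correlation), and library size alone gave 2 and 2. CYR61 was 2.08-fold, the phosphatase DUSP1 2.31-fold (in 3 of 4 batches) and EGR1 2.06-fold lower, and VIP 1.84-fold and CCND1 1.92-fold higher. KIDINS220 (7.48-fold) and LBH (5.35-fold), both of the chromosome 2 part, and LMCD1 (6.85-fold) were among the largest decreases. In all, 312 of 4039 genes were called, 185 higher and 127 lower. Library size alone gave 143 higher and 183 lower, with the median gene moved from −0.02 to −0.11 on the log2 scale, DESeq2 called 187 and the fit without the batch block 173. In this comparison and those of cluster 1 and cluster 2, every list that passed kept its direction and passed under RLE scaling and library size alone. Between cluster 1 and adrenergic-like cells further lists passed only under those scalings: YAP and TAZ targets (adjusted p = 0.0601 with TMM, 0.0401 with RLE, 0.0327 by library size), p53 targets (0.0538, 0.0383 and 0.0327) and ribosomal proteins, with 3 higher and 1 lower (0.217), 1 and 12 (0.00559), and 0 and 22 (4.8e-06).

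Along chromosome 1, in gene order, the 226 genes up to PHGDH had a median log2 fold of −0.06 and the 175 genes from PIAS3 on 0.61, a step of 0.67. Along chromosome 2 the 90 genes up to COMMD1 had a median of −0.44 and the 179 genes from MDH1 on −0.02, a step of 0.43. Each step had a permutation p of 0.001, the smallest that 1000 shuffles can give, and the other 20 autosomes did not pass (lowest permutation p = 0.0519, chromosome 7). Of the 175 genes on the chromosome 1 part 60 were called higher and 1 lower, and of the 90 on the chromosome 2 part 0 higher and 16 lower, while 213 of the 312 called genes lay on other chromosomes. Without the genes of both parts 221 were called, 121 higher and 100 lower. Among 3873 ordered genes, those on no list and not used in the clustering were then counted in all UMIs. The parts had been set from mesenchymal-like cells and cluster 2 with some of the same UMIs. The difference of mesenchymal-like cells in these shares is therefore partly fixed by construction. Of their UMIs, the 137 on the chromosome 1 part took 6.30% ± 0.222 in mesenchymal-like cells against 4.13% ± 0.263 in adrenergic-like cells, 4.19% ± 0.0202 in cluster 1 and 4.22% ± 0.0694 in cluster 2 (SD, n = 4). The 68 on the chromosome 2 part took 2.0% ± 0.0640 against 2.66% ± 0.265, 2.42% ± 0.0548 and 2.45% ± 0.0662. No step was found between adrenergic-like cells and cluster 1 (lowest permutation p = 0.556).

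**Figure D4:**
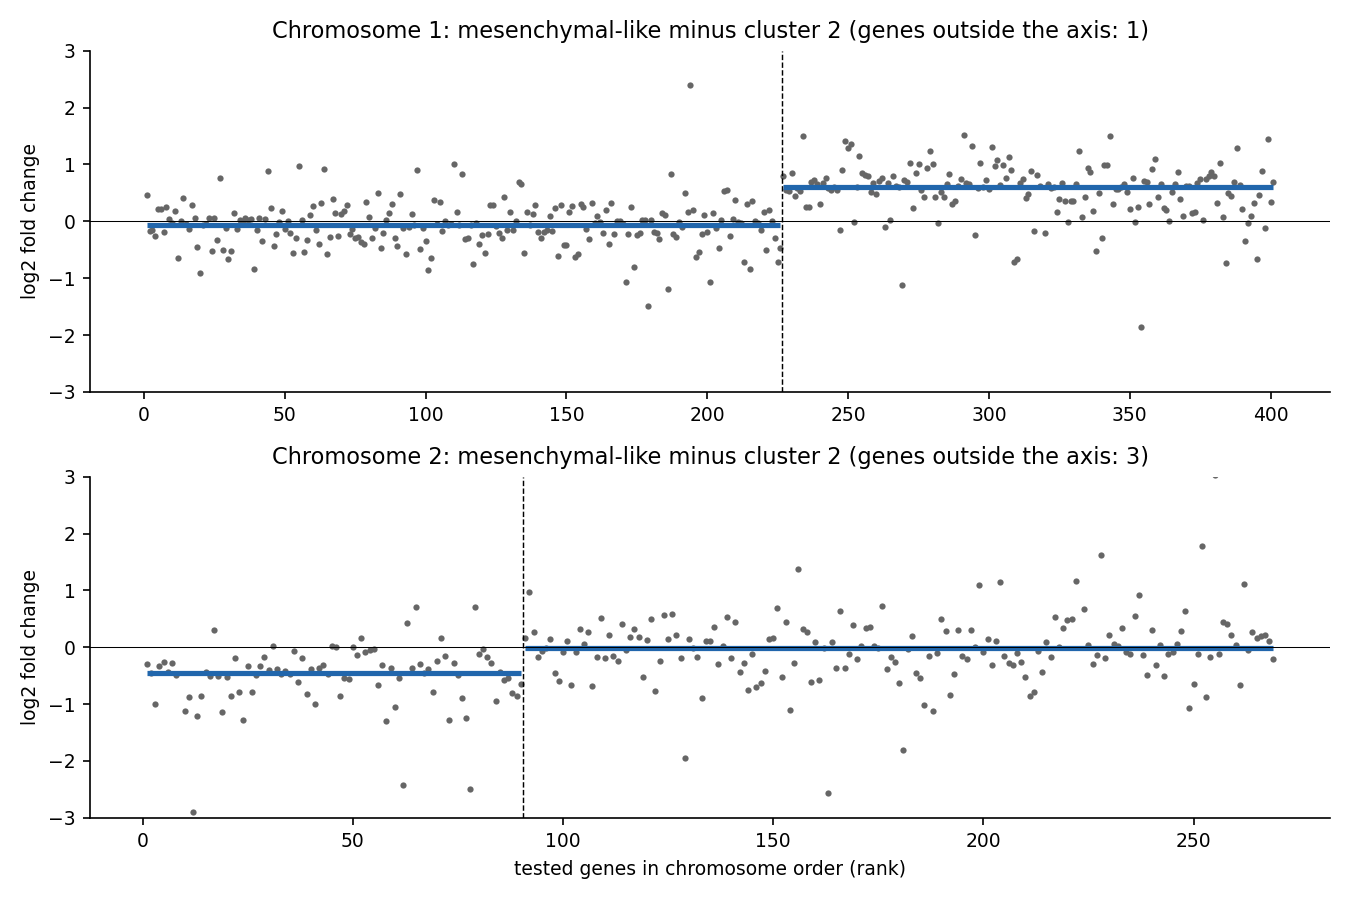
Log2 fold change of genes in order along chromosomes 1 and 2, mesenchymal-like cells minus cluster 2, with lines for the median on each side of the step and a dashed line at the step. The medians moved from −0.06 to 0.61 on chromosome 1 and from −0.44 to −0.02 on chromosome 2, and 1 and 3 genes lay outside the axis.

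**Figure D5:**
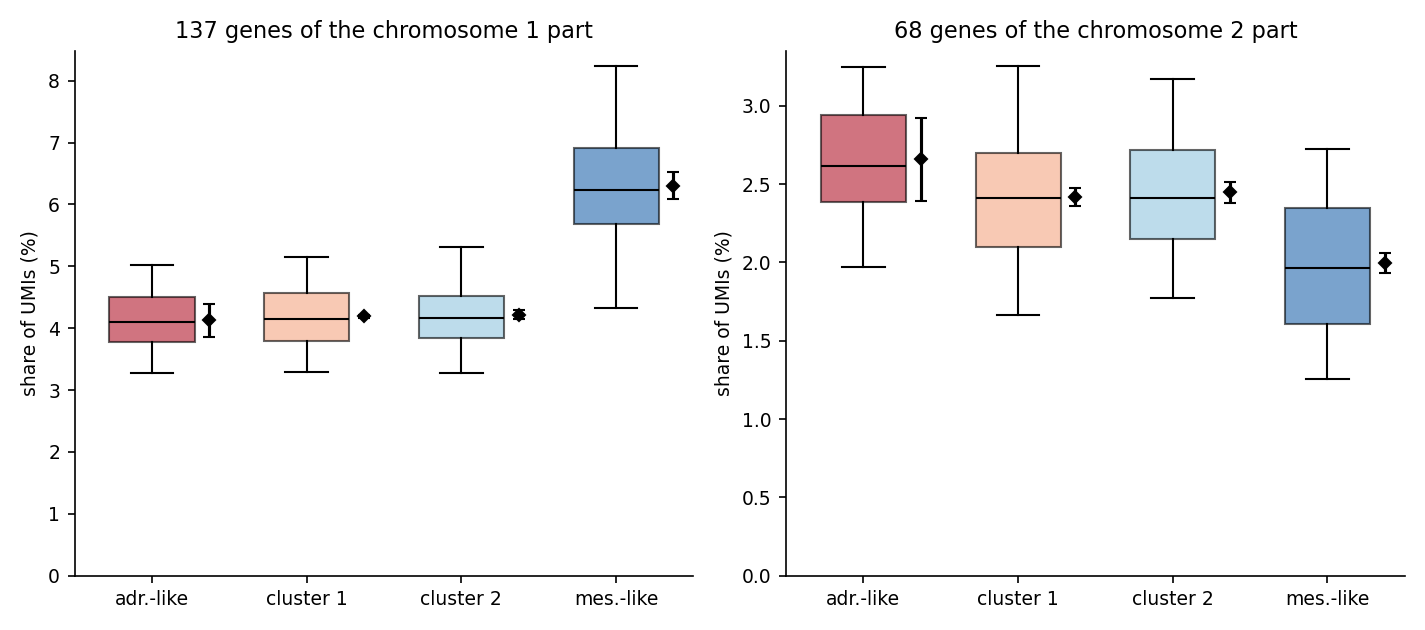
Percent of each cell's UMIs that came from 137 genes of the chromosome 1 part and 68 genes of the chromosome 2 part. Only UMIs of genes on no list and not used in the clustering were counted. Box plots by cluster have whiskers at the 5th and 95th percentiles, and diamonds with error bars give the mean and SD of 4 batches. The parts were set from mesenchymal-like cells and cluster 2 with some of the same UMIs. Mesenchymal-like cells averaged 6.30% and 2.0%, and the other clusters 4.13% to 4.22% and 2.42% to 2.66%.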

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

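None of the values in this part rests on tests chosen after the result was seen. HMP19, among the leading genes of the adrenergic-like cluster, stood at 1290 CPM in batch 2 of the adrenergic-like cells and at 774 to 846 CPM in the other 3 batches. RPS7, a ribosomal protein gene, stood at 1136 CPM in batch 3 of the mesenchymal-like cells and at 1233 to 1247 CPM in the other 3 batches. Each was picked out because its gap to the nearest batch took up most of the range of the 4 batches. Chance picks out about 1 in 20 such sets, which makes 3.6 of the 72 sets examined, and 2 were found.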

How the results depend on the processing

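The tests under at least 2000 UMIs per cell, a new clustering seed, library size alone, classes from all UMIs for genes and lists, without the adrenergic-like cluster, without the chromosome parts, and all those of the 3 added comparisons were chosen after the result was seen. The filters of at least 1000 UMIs and of no minimum were not run, as all cells held more, nor was at least 6 cells per class, which every batch met. The mesenchymal-like share of 21.3% moved to 47.7% at resolution 0.3, 8.59% at 1.0, 55.3% with k-means, 18.9% with lists kept, 18.7% with another UMI split, 19.3% without the top 5 percent of cells and 8.5% with all UMIs, and the adrenergic-like share of 4.00% to 44.7% with k-means. At resolution 0.3 (mesenchymal-like only) and with k-means the classes were chosen by marker score, as no cluster met the naming rule. The log2 difference in UMIs of −0.09 moved to 0.22 with k-means and 0.0677 without the top 5 percent, lay above 0 also at resolution 0.3 (0.01) and at least 2000 UMIs (0.05), and was −0.17 at resolution 1.0. The cycling difference of −7.58 points moved to −17.7 at 3 UMIs, −3.65 at 1 UMI, −18.8 at resolution 1.0, −15.8 with another UMI split, −12 without the top 5 percent, −5.08 with classes from all UMIs and 0.373 with k-means. The marker correlation of −0.216 moved to −0.311 by Pearson, −0.289 without VIM and −0.114 without the adrenergic-like cluster, or −0.225 without both. The 572 genes became 361 at resolution 1.0, 1098 with k-means, 1150 with all UMIs, 1028 with no filter on low counts, 358 with no batch block and 335 in DESeq2. The 7 gene lists became 3 at resolution 1.0, 2 with classes from all UMIs, 11 with no filter and 0 with an estimated correlation. Lists with fewer than 5 tested members had no test, so such counts also depend on which lists were tested. Among single lists, 2 were weaker and 1 stronger at resolution 1.0, 3 weaker with classes from all UMIs and 2 stronger with no filter. No filter gave 1005 genes in place of 643 between cluster 1 and adrenergic-like cells. No batch block gave 173 and DESeq2 187 in place of 312 between mesenchymal-like cells and cluster 2, and 272 and 287 in place of 560 between clusters 2 and 1. The cause of these changes was not tested.

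Leaving out 1 batch at a time gave mesenchymal-like shares of 20.7% to 22%, adrenergic-like shares of 3.52% to 4.22%, a chi-square of 1.07 to 1.66, UMI differences of −0.14 to −0.04, cycling differences of −9.23 to −5.73, correlations of −0.245 to −0.179, 418 to 503 genes and 5 to 7 lists. In the added comparisons it gave 438 to 569 genes for cluster 1, 212 to 258 for mesenchymal-like cells and 357 to 454 for cluster 2, where 357 was without batch 2. With k-means the log2 folds of SERPINH1 (−0.21), TIMP1 (−0.22), HLA-B (−0.25), B2M (−0.80), NPY (0.68) and PDIA4 (−0.21) reversed, as did the interferon list (adjusted p = 0.782), and with no filter on low counts MDK (0.11). K-means draws clusters 1 and 2 into the classes, so its classes are not the same cells. Of the 1140 values of 63 named genes under the alternatives, 1074 kept their direction and side of the threshold, 59 were weaker in 21 genes and 7 reversed. DESeq2 gave 12 of the weaker ones. Of the values of single lists 218 were the same, 13 stronger, 13 weaker (7 with an estimated correlation) and 1 reversed. Depth limits the adrenergic-like class most: a gene with 0 UMIs there may lie as high as 30.5 CPM, against 5.85 CPM in mesenchymal-like cells.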

Other observations

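The comparisons between neighbouring clusters and the tests of steps in gene order and of calls on other chromosomes were chosen after the result was seen. A few genes that the report does not describe set the clusters apart. SLC6A2, the noradrenaline transporter, stood at 125 ± 142 CPM in adrenergic-like cells (SD, n = 4) against 2 UMIs in cluster 1, a ratio of 56.4 (counting interval 12.6 to 519; edgeR adjusted p = 1.07e-06), with the difference in 3 of 4 batches. CPLX1, a complexin of synaptic vesicle release, had a ratio of 122 (18.4 to 5198) in the same direction, in 4 of 4 batches. IGFBP5, which binds insulin-like growth factors, did not follow the order of the marker scores. It stood at 119 ± 51 CPM in adrenergic-like cells, 60.1 ± 27.3 in cluster 1, 3.10 ± 3.61 in cluster 2 and 64.3 ± 18.4 in mesenchymal-like cells. Cluster 2 was lower than cluster 1 with a ratio of 22.1 (5.84 to 187) and lower than mesenchymal-like cells with a ratio of 23.8 (6.10 to 204), each in 4 of 4 batches. CXCL12, a chemokine, was also lower in cluster 2 than in cluster 1, with a ratio of 16 (5.23 to 79.8), and FXYD6, a regulator of the sodium pump, was 12.7-fold lower. RAB3B, a GTPase of vesicle release, was 3.77-fold higher in cluster 2 than in cluster 1 at 142 ± 29.9 against 36.4 ± 4.81 CPM.

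Batches differed as well. In edgeR, 488 of 4039 genes differed between the 4 batches, 213 of them at least 2-fold, with 44 of 68 ribosomal protein genes among the 488. RPL26 stood at 979, 2669, 2491 and 1033 CPM in batches 1 to 4, RPS24 at 312, 1046, 935 and 477, and MGP, a matrix protein, at 113, 394, 387 and 90.2. LDHB stood at 197, 359, 510 and 153 CPM and B2M at 109, 282, 375 and 142. All 4 clusters were present in each batch, and the batch was a block in each comparison.

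The mesenchymal-like cells differed from cluster 2 by steps along chromosomes 1 and 2. A hypothesis is that they are a subclone with other copies of parts of these chromosomes, or cells of another line. In the test of steps against 1000 shuffles of the genes, the steps of 0.67 on chromosome 1 and 0.43 on chromosome 2 each had a permutation p of 0.001, the smallest possible. They lay above and below the 0.58 of 3 copies against 2, so they give no copy number. Chromosome medians also spread more than in random regroupings (permutation p = 0.001, the smallest they can give; the test gave 2 false calls in 20 simulated runs with no shift), although chromosome 1 as a whole lay 0.20 above the rest, under the 0.3 set for this test. That RNA of these chromosomes alone made the cluster was argued against by the 213 genes called elsewhere; with the first seed, clustering without chromosomes 1 and 2 put 51% of the cells in a cluster of which they made up 37.3%, which met the value set for this cause, but leaving out chromosomes 3 and 19 did so too (55.4% and 40.8%). Over 20 seeds the cells stayed together in 20 runs with no chromosome left out, in 19 without chromosomes 3 and 19 (2640 genes) and in 13 without chromosomes 1 and 2 (3525 genes), and came apart in 0, 1 and 6. Subclone and other line stay open, as no DNA was measured, and no biological explanation was tested, since the design has 1 group.

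The adrenergic-like cells stood apart from all other clusters. Other copies of whole chromosomes were argued against: medians spread no more than in random regroupings (permutation p = 0.252), although this test found a simulated shift of chromosome 18 in 12 of 20 runs and of chromosome 7 in 20 of 20. The highest upper bound for a chromosome, 0.44 on chromosome 18, lay below 0.58. Shifts of whole chromosomes smaller than the bounds stay open. Copies of parts stay open, since simulated steps were found in 12 of 20 runs too. After thinning and clustering again, 85.7% of the adrenergic-like cells fell in 1 cluster and made up 90% of it. This lay between the values set for and against depth. At equal UMIs these cells had a median of 17 adrenergic marker UMIs against at most 4 in other clusters. The cluster was named by these markers, so the medians do not decide whether depth was the cause. The median total of adrenergic-like cells, 3538 UMIs, lay between those of cluster 1 (2875) and cluster 2 (3688). No biological explanation was tested.

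Clusters 1 and 2 differed in depth, with medians of 2875 and 3688 UMIs per cell. After thinning to 984 UMIs of the clustering set, the adjusted Rand index of their cells with the new clusters was 0.557. This argued against depth as the whole cause. The new clustering gave only 3 clusters over the 942 kept cells, with an index of 0.501 over all of them. Where the mesenchymal-like cells fell was not counted, so whether they stay apart at equal depth is open. No biological explanation was tested.

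Other divisions of the 8 summed libraries into 4 and 4, fitted without the batch block, were compared with the real ones. In each of the 4 comparisons 1 of 35 divisions, the real one, called as many genes. The clusters were made from the expression of the same cells, so a division by cluster was bound to call the most genes. The count therefore cannot decide whether the clusters themselves arose by chance. The real division called 358 genes between mesenchymal-like and adrenergic-like cells and the highest other 2; with the batch block and the 8 divisions that part each batch, 572 and 0. It called 386 between cluster 1 and adrenergic-like cells (highest other 2), 137 between mesenchymal-like cells and cluster 2 (highest other 9) and 288 between clusters 2 and 1 (highest other 8).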
